A study of Mus musculus with 6 samples.

How the data were processed

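Bone marrow mononuclear cells (BMMNCs) of wild-type mice were grown for 10 days on 1 of 2 scaffold materials, PCL or hHVS, and their messenger RNA was sequenced. PCL is the usual abbreviation of polycaprolactone, a synthetic biodegradable polyester; the labels do not spell out hHVS, which is kept here as a name. The tables hold mouse genes only, so whether a scaffold carried RNA of its own, from another species or not, could not be checked. Each material had 3 libraries, numbered 1 to 3 in the sample titles, and groups were taken from those titles. Per the labels' protocols, total RNA was extracted with a column kit, polyadenylated RNA was captured with oligo-dT beads and fragmented, and libraries were prepared with a stranded mRNA kit. The labels do not say that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

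The authors deposited a table of estimated counts per gene and a table of FPKM values per gene, each with 51912 Ensembl gene records and 6 library columns. Per the submitters' processing notes, the tools were FastQC, MultiQC, STAR and featureCounts, and the genome build was mm10; versions, and which tool produced each table, are not given in the sources used here. The deposited count table had been assumed to hold raw read counts when the tests were chosen, but its whole numbers behaved as estimated counts rounded from coverage. The value 4 filled 6544 cells of the table, against 2701 cells with 3 and 1483 with 5, and 8 filled 3210, against 1302 with 7 and 857 with 9. From these peaks 1 sequenced fragment was taken as worth about 4 units. The value 1 filled more cells still (6904), and 2 filled 3737, so not every value is a whole number of such fragments. Within a gene the deposited FPKM values were proportional to the deposited estimated counts: the median absolute log2 deviation fell from 0.03 at 10 to 30 units to 4.36e-05 at 10000 units and above. The values were used as deposited, since they were already whole numbers, and an alternative on a scale of about 1 unit per fragment was added after this was seen. Because units overstate the number of fragments, counting noise was left to the dispersion estimated from the replicates. Whether the counting used the strand is not given in the sources used here, so values of overlapping genes on opposite strands are uncertain.

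Library totals ranged from 72.1 to 83.6 M units, or about 18.0 to 20.9 M fragments. A floor of 3 fragments (12 units) corresponds to between 0.144 and 0.166 CPM (counts scaled to a library total of 1e+06) in a single library, and to 0.0545 CPM over the PCL group and 0.0505 CPM over the hHVS group. Floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

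Genes were filtered with filterByExpr (minimum count 10), library sizes were adjusted with TMM factors (0.959 to 1.05), and hHVS was compared with PCL by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with group as the only term. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and log2 fold changes are hHVS minus PCL with standard errors (SE). Levels are TMM-adjusted CPM as mean ± SD over 3 libraries. Of 26793 genes with any count, 16364 were tested. The common biological coefficient of variation was 24.0%. The 6 libraries were distinct: within groups, the chi-square per gene between 2 libraries was at least 11.4.

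Before the data were examined, 40 gene lists (739 genes, 734 of them in the tables) were fixed for cell types, pathways and signs of RNA quality. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided and adjusted over the 40 lists; the test was repeated with an estimated correlation and with the rotation test fry. Members past the threshold were also counted with p adjusted over the list alone. Gene names came from the tables, and 98 symbols belonged to more than 1 gene record, so a list can hold more records than symbols. Coordinates came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by Ensembl identifier for 51633 records (99.5%).

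Genes were named by a rule fixed with the lists. It took the 10 largest rises and the 10 largest falls past the threshold with at least 10 CPM in the higher group, no overlap between the libraries of the groups, and a symbol that is not a clone or predicted-gene name. For every list it took up to 3 members past the threshold with at least 1 CPM in the higher group and the largest change, or the most abundant member where none passed. It always took Nkx2-5, Gata4, Mef2c, Tnnt2, Myh6, Actc1, Mki67, Pcna and Ptprc. The values of 1 gene that the rule named are not reported here. Shares of each library's counts were compared with an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1. Shared sequence was measured as the share of a gene's 50-base words that also occur in annotated transcripts of another gene.

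The alternatives tried were other library scalings (RLE, upper quartile, library totals only), no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. The scale of about 1 unit per fragment and the fit without mitochondrially encoded genes were added after the data were seen. The gene test was tested on simulated counts drawn from the means and library sizes of these libraries for hHVS minus PCL, at 4 units per fragment and with 13583 genes tested. It called 54 of 100 genes changed by a log2 fold of 1 and 87 of 99 changed by a log2 fold of 2. It also called 19 of 13360 unchanged genes. These false calls were a larger share of all calls than the adjusted p threshold is meant to allow. At 1 unit per fragment the gene test called 69 of 99 and 89 of 97 such changed genes, and 17 of 13183 unchanged ones. The false share was above the aim of the threshold there too. The calls reported here may therefore hold more false ones than the threshold implies. With no gene changed the gene test called 0 of 13587 at 4 units per fragment, and 3 of 13397 at 1 unit per fragment. Figures were drawn with matplotlib 3.10.9.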

Results

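The data are 6 RNA-seq libraries of mouse bone marrow mononuclear cells, the leukocyte, progenitor and stromal fraction of marrow that remains after granulocytes and most red cells are removed. They were cultured for 10 days on hHVS (n = 3) or on PCL (n = 3). Estimated counts totalled 74.1, 72.1 and 74.1 M units in PCL replicates 1, 2 and 3. In hHVS replicates 1, 2 and 3 they totalled 75.1, 83.6 and 78.8 M units, with about 4 units per sequenced fragment. Between 20885 and 21210 genes had counts in each library. The most abundant transcripts were Gpnmb, mt-Co1, Ctsb, Fth1, Ctsd, Ftl1, Psap, Lyz2, Lpl and Apoe, most of them abundant in macrophages. The macrophage genes Csf1r and Cd68 were near 2000 CPM in both groups: Csf1r was at 2006 ± 59.7 CPM on hHVS and 2225 ± 77.9 CPM on PCL, and Cd68 at 2162 ± 47.3 and 2192 ± 114 CPM (mean ± SD of unadjusted CPM, n = 3). In a principal component analysis of log2 CPM, the first component held 28.3% of the variance and separated the groups, with PCL libraries from -39.7 to -30.5 and hHVS libraries from 31.7 to 40.1. The second held 23.3% and set PCL replicate 3 (-53.6) and hHVS replicate 2 (-32.1) apart from the other libraries (10.4 to 31.8), across both groups.

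The comparison asked how the scaffold affects the cells, and the series names proliferation and cardiomyogenic differentiation as the properties studied. Where paired values are given without a group, the first is hHVS and the second PCL. On hHVS, the macrophage scavenger receptor gene Marco rose 12.2-fold, from 8.69 ± 2.82 CPM on PCL to 106 ± 39.7 CPM, and Cd5l, which encodes a scavenger protein secreted by macrophages, rose 5.06-fold, from 514 ± 145 to 2600 ± 495 CPM (SD, n = 3). Protein genes of the mitochondrial genome were higher as a list (camera adjusted p = 1.36e-10 with the preset correlation, 0.279 with an estimated correlation). Mcoln3, a lysosomal cation channel gene, fell from 49.6 ± 17.0 to 7.22 ± 0.842 CPM, and Dcstamp, which is needed for fusion of osteoclasts and macrophages, fell from 41.3 ± 17.7 to 7.57 ± 1.23 CPM. Of the 13 genes tested in the list of osteoclasts and fused macrophages, however, 9 had a positive log2 fold change. The cardiomyocyte genes Actc1, Myh6, Tnnt2 and Nkx2-5 were at or near 0 on both scaffolds, although a few other sarcomere genes had low counts in every library, and neither Mki67 nor Pcna passed with edgeR, while DESeq2 put both past the threshold in opposite directions.

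Of 16364 genes tested with edgeR's quasi-likelihood test, 92 were higher and 49 lower on hHVS at an adjusted p under 0.05, together 0.862% of the genes tested. Of these, 47 higher and 30 lower genes had a log2 fold change of at least 1 in size, and 128 of the 141 were protein-coding. At an unadjusted p under 0.05, 2149 of the 16364 genes passed, where a share of 0.05 would pass by chance alone. Counts of list members at an unadjusted p are to be read against this count over all genes. The libraries of the groups did not overlap in any of the 141 genes, and did not overlap in 3364 genes overall (20.6%, against 10% by chance). With library totals in place of TMM factors the split was 71 higher and 74 lower. The count depended on single libraries: it was 33 higher and 22 lower without PCL replicate 1, 31 and 14 without PCL replicate 2, 20 and 12 without hHVS replicate 1, 45 and 18 without hHVS replicate 2, and 23 and 10 without hHVS replicate 3. Without PCL replicate 3 it was 94 higher and 60 lower, more than with all libraries.

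Among the 10 largest rises, Marco (chr 1:120474538-120505024) had a log2 fold change of 3.61 ± 0.37 (SE, adjusted p = 0.0105, edgeR) and Cd5l (chr 3:87357881-87371073) of 2.34 ± 0.23 (adjusted p = 0.00899, edgeR). Vcam1, an adhesion molecule gene, rose from 3.84 ± 0.895 to 18.5 ± 9.69 CPM (adjusted p = 0.0497, edgeR). The transporter gene Slc16a9 rose 4.38-fold and the glutathione transferase gene Gstm2 3.33-fold (adjusted p = 0.00333 for both, edgeR). The collagenase gene Mmp8 (chr 9:7558456-7568485) rose from 56.4 ± 3.15 to 153 ± 10.6 CPM (adjusted p = 0.00333, edgeR), and Mmp27, a neighbouring metalloproteinase gene, rose 2.62-fold. Bst1, a surface ADP-ribosyl cyclase gene, rose 2.80-fold, the prostacyclin receptor gene Ptgir 2.53-fold and complement C3 2.43-fold. Each of these 10 genes was higher in all 3 hHVS libraries than in any PCL library, as the rule that named them required.

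Among the largest falls, Mcoln3 (chr 3:146117450-146141806) had a log2 fold change of -2.78 ± 0.25 (adjusted p = 0.0083, edgeR) and Dcstamp (chr 15:39745930-39760938) of -2.45 ± 0.30 (adjusted p = 0.0165, edgeR). Sh2d1b1, a lymphocyte signalling adaptor gene that shares 13.4% of its 50-base words with Sh2d1b2, was at 5.42 CPM on hHVS and 21.0 CPM on PCL. Tmem178 fell with a log2 fold change of -1.86, and the glucose transporter gene Slc2a6 with one of -1.64. The adhesion molecule gene L1cam (log2 fold change -1.41), the leukocyte actin-binding gene Lsp1 (-1.41), the phosphatase gene Dusp1 (-1.28) and the intermediate filament gene Nes (-1.20) also fell. These 9 genes were lower in all 3 hHVS libraries than in any PCL library, again by the rule that named them.

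Leaving out single libraries removed calls of several of these genes. Slc16a9, Gstm2, Mmp8, Bst1, Mmp27, Ptgir and Mcoln3 stayed past the threshold whichever library was left out. Marco and Cd5l missed it without PCL replicate 1 (adjusted p = 0.053 and 0.0502, edgeR), and Vcam1 and C3 missed it whichever library was left out (highest adjusted p = 0.154 and 0.149). Of the falls, Dcstamp missed it whichever hHVS library was left out (up to 0.0871), Sh2d1b1 and Dusp1 without hHVS replicate 1 or 3 (up to 0.0684 for both), and Lsp1 without PCL replicate 2 or hHVS replicate 1 or 3 (up to 0.0675). Tmem178 (up to 0.138), L1cam (0.0871) and Nes (0.185) passed only without PCL replicate 3 among the 6 leave-outs, and Slc2a6 (up to 0.171) only without PCL replicate 1.

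**Figure D1:**
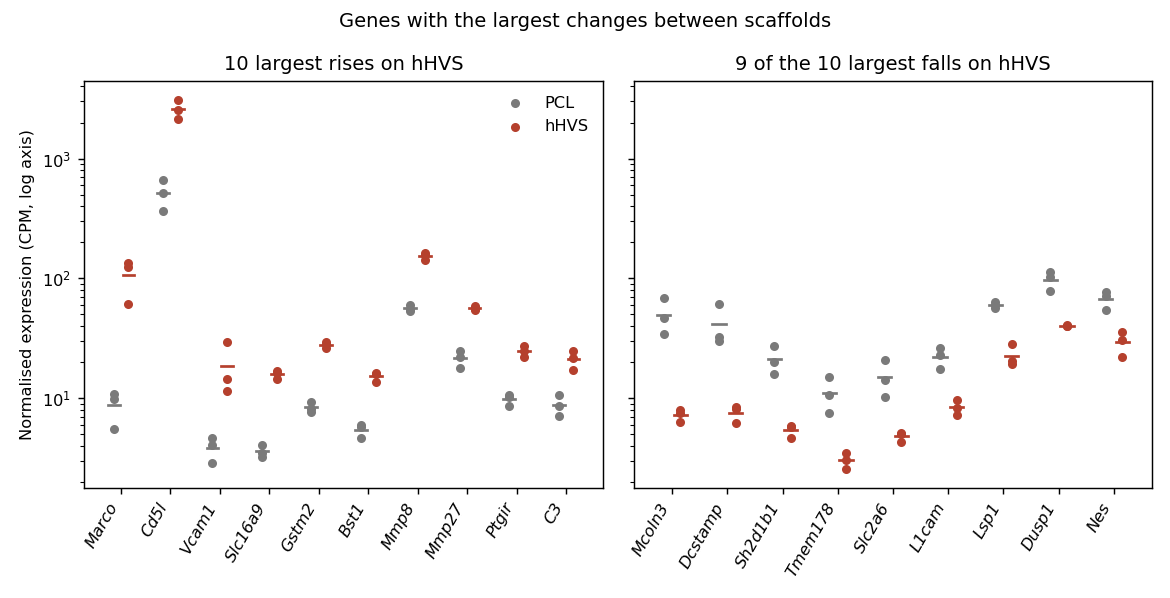
TMM-adjusted CPM on a log axis for the 10 genes with the largest rise (left) and 9 of those with the largest fall (right) on hHVS; points are single libraries (grey PCL, red hHVS, n = 3 each) and bars are group means. Marco lies between 60.7 and 134 CPM on hHVS and between 5.48 and 10.8 CPM on PCL. In each of the 19 genes the libraries of the groups do not overlap, which the rule that chose them required.

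On proliferation, neither cell cycle list held a gene that passed with edgeR. Of the 25 genes of the G1 to S and DNA replication list, 0 rose and 0 fell, also when adjusted over the list alone, and camera gave an adjusted p of 0.563. With edgeR 1 of the 25 had an unadjusted p under 0.05, DESeq2 put 1 past the threshold and limma-voom 0. The direction of this list turned from down to up without PCL replicate 3 (adjusted p = 0.208) or hHVS replicate 1 (0.73). Pcna, the replication clamp gene, was at 514 ± 36.9 CPM on hHVS and 637 ± 35.3 CPM on PCL (log2 fold change -0.31 ± 0.08, adjusted p = 0.16, edgeR). Of the 28 genes of the G2 and mitosis list, 0 rose and 0 fell, with 4 at an unadjusted p under 0.05 in edgeR, 1 past the threshold in DESeq2 and 0 in limma-voom. A positive log2 fold change was seen for 23 of them (median 0.13; camera adjusted p = 0.028, up). That call was lost with an estimated correlation (adjusted p = 0.854 with an estimated correlation). It was also lost without PCL replicate 1 (adjusted p = 0.234), PCL replicate 2 (0.0985), hHVS replicate 2 (0.713) or hHVS replicate 3 (0.0899). With 1 library left out the median ranged from 0.02 (without hHVS replicate 2) to 0.25 (without hHVS replicate 1). Mki67, a marker of cycling cells, was at 242 ± 25.7 CPM on hHVS and 170 ± 26.5 CPM on PCL (log2 fold change 0.51 ± 0.13, adjusted p = 0.162, edgeR). DESeq2 put both Mki67 and Pcna past the threshold, in these opposite directions.

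On cardiomyogenic differentiation, 8 of the 30 genes of the cardiomyocyte and sarcomere list were expressed enough to be tested, and 0 rose or fell (camera adjusted p = 0.183). In edgeR 0 had an unadjusted p under 0.05, and 0 passed with DESeq2 or limma-voom. Actc1 had 0 counts in all 6 libraries, which allows up to 0.0505 CPM over the hHVS group and 0.0545 CPM over the PCL group. The highest value in any library was 0.108 CPM for Myh6, 0.054 CPM for Tnnt2 and 0.0533 CPM for Nkx2-5, all below the floor of a single library, and 0.364 CPM for Gata4. A difference in Actc1, Myh6, Tnnt2 or Nkx2-5 was not detectable at this depth. Gata4 exceeded that floor but was too low to be tested. Other sarcomere genes of the list, named after their values were seen, had counts in all 6 libraries: Tnni3 at 1.52 and 1.63 CPM, Tnnc1 at 0.66 and 0.546 CPM, Mybpc3 at 0.607 and 0.557 CPM and Ttn at 0.627 and 0.389 CPM (means of unadjusted CPM). Mef2c, which macrophages also express, was at 24.1 ± 2.29 CPM on hHVS and 21.3 ± 4.03 CPM on PCL (log2 fold change 0.18 ± 0.15, adjusted p = 0.659, edgeR). The most abundant member of the list was Atp2a2, a calcium pump gene expressed in many cell types, at 250 ± 8.66 and 223 ± 17.7 CPM (adjusted p = 0.44, edgeR).

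The mitochondrially encoded list had the smallest p of the 40 lists in camera with the preset correlation, though not with an estimated correlation or with fry. Of its 13 protein genes, 5 rose and 0 fell. With p adjusted over the list alone, 12 rose (median log2 fold change 0.53, camera adjusted p = 1.36e-10, up). The adjusted p was 0.279 with an estimated correlation. mt-Nd5, a subunit of complex I, rose from 2021 ± 128 to 3476 ± 301 CPM (adjusted p = 0.0131, edgeR), and mt-Co1, a subunit of complex IV, from 11279 ± 225 to 19380 ± 2548 CPM (adjusted p = 0.0225, edgeR). mt-Nd4l rose from 181 ± 12.6 to 289 ± 31.3 CPM, and nearly all of its 50-base words (98.8%) also occur in the nuclear pseudogene Gm10222. Of the words of mt-Co1, 51.1% occur in other genes, among them the nuclear pseudogenes Gm29216 and Gm13340. The other members that rose, named here after their values were seen, were mt-Nd4, with 62.2% of its words in the pseudogene Gm28439, and mt-Nd6, with 0%, while mt-Nd5 had 7.61%. Outside the list, the mitochondrial ribosomal RNA genes mt-Rnr1 (log2 fold change 0.76, adjusted p = 0.00899, edgeR) and mt-Rnr2 (0.62, adjusted p = 0.0455, edgeR) also rose. mt-Rnr1 passed whichever library was left out. The pseudogenes Gm10222, Gm28439 and Gm13340 were called higher as well, so the count of higher genes may hold the same mitochondrial reads more than once. mt-Nd5 missed the threshold without PCL replicate 2 or hHVS replicate 1 or 3 (adjusted p up to 0.0827), and mt-Co1 (up to 0.134) and mt-Nd4l (up to 0.167) passed only without hHVS replicate 2 among the 6 leave-outs. All genes of the mitochondrial genome together held 3.90% ± 0.298 of counts on hHVS and 2.66% ± 0.152 on PCL (SD, n = 3; exact two-sided permutation p = 0.1, the smallest this design allows). The 10 most abundant genes held 14.2% ± 0.712 and 12.1% ± 0.536 (exact permutation p = 0.1), and haemoglobin genes under 0.001% in every library. Of the 24 nuclear-encoded genes of oxidative phosphorylation, 0 rose or fell (camera adjusted p = 0.931), 0 had an unadjusted p under 0.05 in edgeR, and 0 passed with DESeq2 or limma-voom, with Atp5b at 466 ± 14.4 and 468 ± 24.4 CPM.

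**Figure D2:**
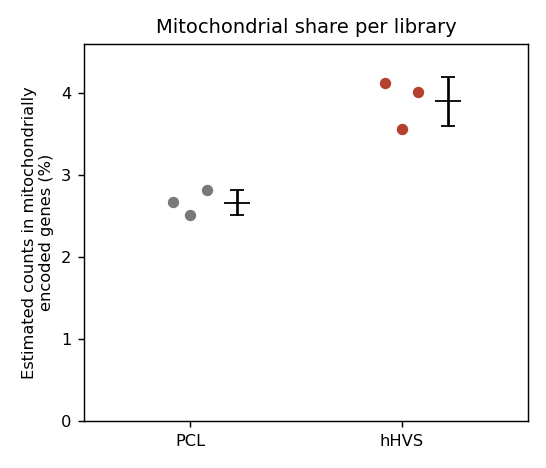
Percent of each library's estimated counts in genes of the mitochondrial genome; points are libraries (n = 3 per group), and the black marks beside them are the mean ± SD. The hHVS libraries lie between 3.56% and 4.12% and the PCL libraries between 2.51% and 2.81%.

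Of the lists named for macrophages, those of monocytes and macrophages and of alternative activation were higher on hHVS with the preset correlation. Inflammatory activation (camera adjusted p = 0.676) and osteoclasts and fused macrophages (0.541) did not pass. Pathway lists of lipid handling, lysosome, and oxidative stress and iron were higher as well. The median log2 fold change was 0.12 for monocytes and macrophages (mean 0.39) and 0.31 for alternative activation. It was 0.19 for lipid handling, 0.13 for lysosome and 0.15 for oxidative stress and iron. In the monocyte and macrophage list (24 gene records tested), 2 rose and 0 fell. When adjusted over the list alone, 9 rose and 2 fell (camera adjusted p = 0.023, up). The adjusted p was 0.279 with an estimated correlation. The genes that rose were Marco and Vsig4, a complement receptor gene of resident macrophages, which was at 1.81 ± 0.468 CPM on hHVS and 0.14 ± 0.057 CPM on PCL, close to the floor of a library. In the alternative activation list (15 tested), 2 rose and 0 fell. With p adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.0135, up; 0.279 with an estimated correlation). The genes that rose were the folate receptor gene Folr2, at 97.8 ± 12.7 and 42.7 ± 6.78 CPM, and the interleukin-4 receptor gene Il4ra, 1.35-fold. Of 18 lipid uptake, storage and efflux genes, 1 rose, Gpnmb, which encodes a membrane glycoprotein of lipid-laden macrophages, from 17447 ± 330 to 23649 ± 1593 CPM. When adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.00557, up; 0.279 with an estimated correlation). Of 24 lysosome genes, 0 rose or fell over all genes in edgeR (9 at an unadjusted p under 0.05; 5 past the threshold in DESeq2 and 0 in limma-voom) and 5 rose when adjusted over the list alone (camera adjusted p = 0.00262, up; 0.384 with an estimated correlation), with Ctsb at 15552 ± 237 and 14594 ± 665 CPM. Of 19 oxidative stress and iron genes, 1 rose, the transferrin receptor gene Tfrc, from 173 ± 5.27 to 413 ± 41.1 CPM (adjusted p = 0.00333, edgeR). With p adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.0178, up; 0.279 with an estimated correlation). The monocyte and macrophage list missed the threshold without PCL replicate 1 or 3 or hHVS replicate 1 or 2 (adjusted p up to 0.0905), the alternative activation list without PCL replicate 1 or hHVS replicate 2 or 3 (up to 0.127), the lysosome list without PCL replicate 1 (0.0507) and the oxidative stress list without PCL replicate 1 (0.0807) or hHVS replicate 1 (0.0665). Tfrc passed whichever library was left out, Vsig4 missed the threshold without PCL replicate 1 or 2 or hHVS replicate 1 (up to 0.0684), Folr2 without 4 of the 6 libraries (up to 0.0767), Il4ra without 5 (up to 0.193) and Gpnmb whichever was left out (up to 0.241).

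Cholesterol biosynthesis genes were lower on hHVS as a list. All 21 tested had a negative log2 fold change with TMM factors (median -0.17, camera adjusted p = 3.57e-04, down). The adjusted p was 0.279 with an estimated correlation. This list, the lipid list, the mesenchymal stromal list and the mitochondrially encoded list stayed past the threshold whichever library was left out. With fry the mesenchymal stromal list missed it (adjusted p = 0.0717), while the others passed (adjusted p up to 0.0439).

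Genes of stromal cells and their matrix were lower as lists, and varied between libraries of a group. Of 22 fibrillar and basement membrane matrix genes, 0 passed over all genes in edgeR (5 at an unadjusted p under 0.05; 4 past the threshold in DESeq2 and 0 in limma-voom) and 1 fell when adjusted over the list alone. Of the 22, 20 had a negative log2 fold change (median -1.27, camera adjusted p = 8.94e-04, down; 0.682 with an estimated correlation). The call was lost without PCL replicate 1 (median -0.85, adjusted p = 0.0895) or hHVS replicate 2 (median -0.33, adjusted p = 0.0682), so the size of the difference depends on single libraries. The most abundant member, the laminin gene Lamc1, was at 56.9 ± 1.51 and 51.0 ± 8.99 CPM. Of 15 mesenchymal stromal genes, Vcam1 rose and Nes fell. When adjusted over the list alone, 1 rose and 4 fell (camera adjusted p = 0.00262, down; 0.279 with an estimated correlation). All 10 smooth muscle and myofibroblast genes tested had a negative log2 fold change and 0 passed in edgeR, DESeq2 or limma-voom (camera adjusted p = 0.477), with Tpm1 at 76.7 ± 3.87 and 84.5 ± 29.6 CPM. This list passed as lower without PCL replicate 3 (median -0.94, adjusted p = 0.0151) and turned to higher without PCL replicate 1 (median 0.15, adjusted p = 0.764).

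Immune response lists differed in both directions. Of 23 interferon response genes, 1 rose, the guanylate-binding protein gene Gbp5, from 0.932 ± 0.0713 to 2.78 ± 0.525 CPM. With p adjusted over the list alone, 7 rose (camera adjusted p = 0.00262, up; 0.681 with an estimated correlation), and the call was lost without hHVS replicate 2 (0.0682). Of 11 MHC class II genes, 0 passed over all genes in edgeR (4 at an unadjusted p under 0.05; 1 past the threshold in DESeq2 and 0 in limma-voom) and 4 fell when adjusted over the list alone (camera adjusted p = 0.0178, down; 0.689 with an estimated correlation), with Ctss at 4445 ± 369 and 5095 ± 671 CPM. That call was lost without PCL replicate 2 (0.0985) or hHVS replicate 1 (0.0665). Of 19 inflammatory activation genes, 0 passed in edgeR (4 at an unadjusted p under 0.05; 1 past the threshold in DESeq2 and 0 in limma-voom; camera adjusted p = 0.676), with the chemokine gene Ccl3 at 41.9 and 39.1 CPM. Of 16 complement genes, C3 and C1ra rose and 0 fell. When adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.75). C1ra shares 50.8% of its 50-base words with C1rb and a pseudogene.

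Of 19 matrix protease genes, 1 rose, Mmp8, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0434, up; 0.305 with an estimated correlation). Mmp8, a neutrophil collagenase, was also the gene that passed among 16 neutrophil genes (camera adjusted p = 0.0456, up; 0.279 with an estimated correlation). Of 20 apoptosis and p53 genes, Zmat3 rose 1.41-fold and 2 rose when adjusted over the list alone (camera adjusted p = 0.0313, up; 0.279 with an estimated correlation). Of 6 mast cell, basophil and eosinophil genes, 0 passed over all genes in edgeR (2 at an unadjusted p under 0.05; 1 past the threshold in DESeq2 and 0 in limma-voom) and 1 fell when adjusted over the list alone (camera adjusted p = 0.0178, down; 0.279 with an estimated correlation), with Ccr3 at 36.3 and 34.7 CPM. Of 25 cytosolic ribosomal protein genes, 0 passed in edgeR, DESeq2 or limma-voom (median -0.10, camera adjusted p = 0.0341, down; 0.861 with an estimated correlation), with Rplp0 at 660 and 764 CPM. Without PCL replicate 3 the median was 0.01 and the adjusted p 0.94. The ribosomal call was also lost without PCL replicate 2 or hHVS replicate 2 or 3 (adjusted p up to 0.206), the protease call on leaving out any library but PCL replicate 2 (up to 0.103), the neutrophil call on leaving out any but hHVS replicate 3 (up to 0.358), the p53 call without PCL replicate 1 or 3 or hHVS replicate 1 or 2 (up to 0.103) and the mast cell call without PCL replicate 2 (0.0579) or hHVS replicate 2 (0.0705). Zmat3, Gbp5, C1ra and Epor missed the threshold whichever library was left out (adjusted p up to 0.189, edgeR). In all, 17 of the 40 lists passed with the preset correlation, 11 up and 6 down. With an estimated correlation 0 passed after adjustment and 4 had an unadjusted p under 0.05. With fry 13 passed, 10 of them among the 17. Not passing with fry were the matrix (adjusted p = 0.39), mesenchymal stromal (0.0717), interferon (0.24) and MHC class II (0.354) lists. The neutrophil (0.0869), ribosomal (0.594) and G2 and mitosis (0.594) lists did not pass with fry either.

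The other lists did not pass with camera. With fry, the T and NK cell list (adjusted p = 0.0071) and the stem and progenitor list (0.0471) passed, both down. The heat shock and immediate early list (0.0449) also passed as down, though its median log2 fold change was 0.0038. Members of each moved both ways. A positive log2 fold change was seen for 3 of 7 T and NK cell, 3 of 9 stem and progenitor and 9 of 19 heat shock genes. The T and NK cell list holds Cd3g, which had 0 counts on hHVS and 33 units on PCL. Member calls that follow are from edgeR with p adjusted over all genes, and list values are from camera. Among these lists, Tfrc and the erythropoietin receptor gene Epor rose of 11 erythroid genes (camera adjusted p = 0.678), Spp1, the osteopontin gene, rose from 882 ± 146 to 1733 ± 274 CPM of 6 osteoblast genes (0.757), Dcstamp fell of 13 osteoclast genes (0.541), Tgfbi fell from 249 ± 8.85 to 134 ± 13.6 CPM of 20 TGF-beta and BMP genes (0.633), Dusp1 fell of 19 heat shock and immediate early genes (0.508), and Vcam1 rose of 22 integrin and adhesion genes (0.474). Dcstamp does not stand for its list: 9 of the 13 osteoclast genes had a positive log2 fold change (median 0.125). When adjusted over that list alone, 2 rose and 1 fell. No member passed in edgeR in the lists of angiogenic factors (0.634, Igf1 at 1595 and 1464 CPM), endothelial cells (0.563, Vwf at 56.1 and 84.1 CPM), megakaryocytes (0.634), dendritic cells (0.634, Itgax at 475 and 461 CPM), B cells (0.847, Blnk at 155 and 181 CPM), T and NK cells (0.215, Il7r at 431 and 481 CPM), stem and progenitor cells (0.074, Cd48 at 123 and 136 CPM), adipocytes (0.847, Lpl at 10811 and 9899 CPM), glycolysis and hypoxia (0.634, Pkm at 1842 and 1888 CPM), the unfolded protein response (0.424, Hspa5 at 584 and 605 CPM) or the sex-linked check (0.75, Ddx3y at 97.3 and 94.0 CPM). With p adjusted over each of these lists alone, 1 angiogenic and 1 T and NK cell gene fell, 1 dendritic gene rose, and 1 adipocyte gene rose and 1 fell. DESeq2 put 1 angiogenic, 1 dendritic, 2 adipocyte and 2 glycolysis and hypoxia genes past the threshold, and limma-voom 1 T and NK cell gene. The median and the camera direction, or the median and the mean, differed in sign for the endothelial, dendritic, megakaryocyte, osteoclast and heat shock lists. Spp1 missed the threshold without 5 of the 6 libraries (adjusted p up to 0.167, edgeR), and Tgfbi without hHVS replicate 1 (0.0575). Ptprc, the gene of the pan-leukocyte antigen CD45, was at 535 ± 65.7 CPM on hHVS and 596 ± 106 CPM on PCL (log2 fold change -0.16 ± 0.14, adjusted p = 0.681, edgeR).

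**Figure D3:**
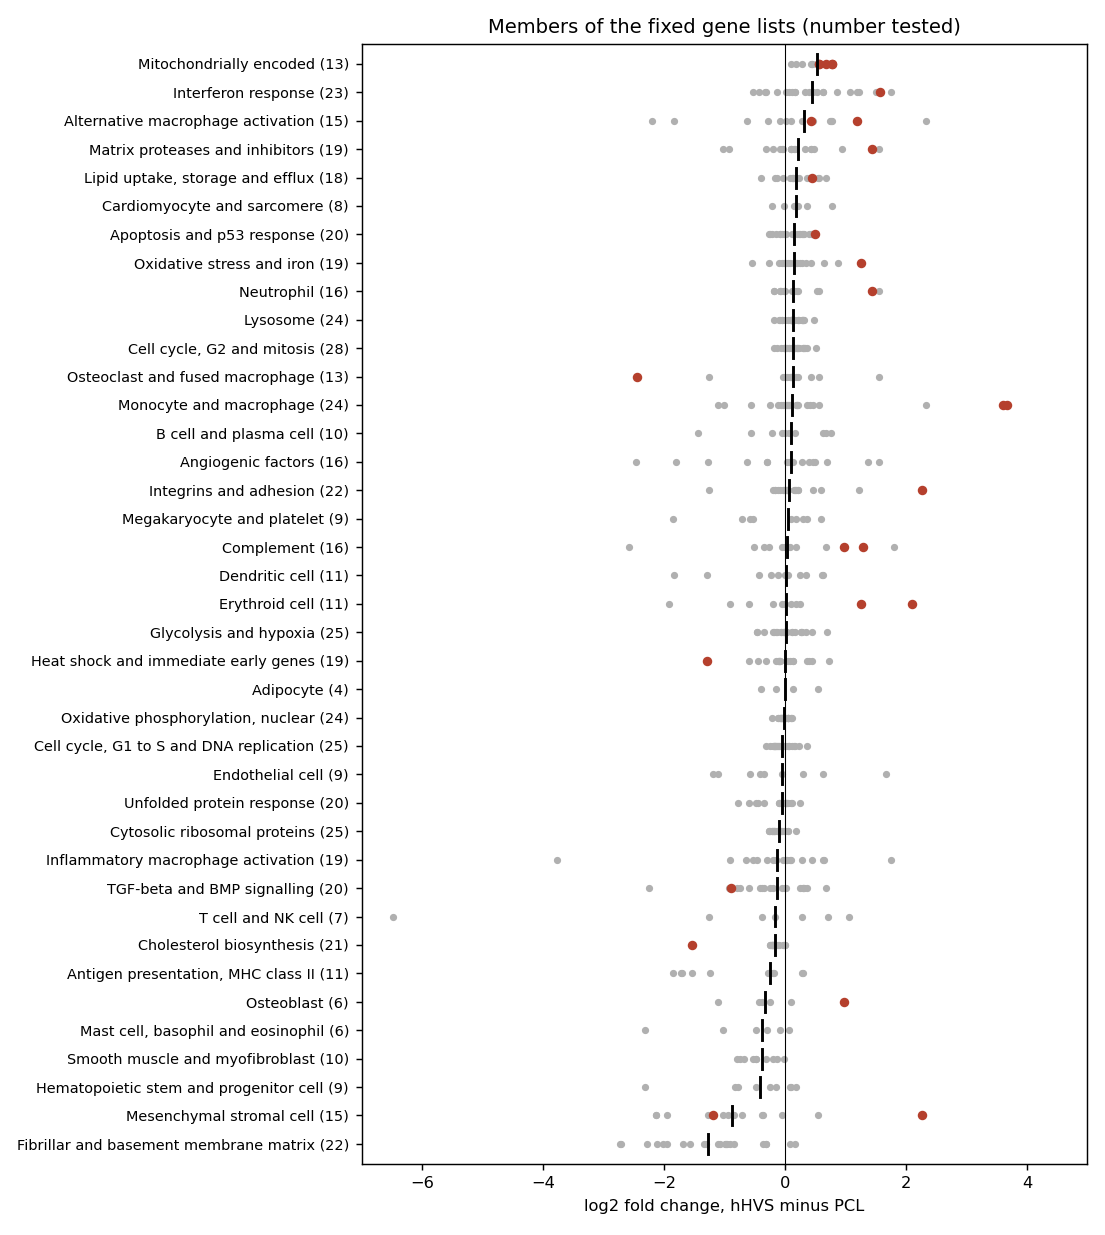
Log2 fold change (hHVS minus PCL) of every tested member of the fixed gene lists, without the sex-linked check; the number tested is in parentheses, red points passed the test over all genes, grey points did not, and black bars are list medians. The mitochondrially encoded list has the highest median (0.53), though without PCL replicate 3 it is at 0.574 and the interferon list at 0.576. The matrix list has the lowest (-1.27, but -0.33 without hHVS replicate 2, when the mesenchymal stromal list is lower at -0.50). The point farthest to the left is Cd3g, which had 0 counts on hHVS, so its position depends on the prior count of the fit.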

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

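The scale of about 1 unit per fragment (101 genes higher and 64 lower) and the fit without mitochondrially encoded genes (68 and 41) were chosen after the data were seen. All other alternatives were planned. All 141 genes past the threshold had the same sign wherever they were tested in each of the 19 alternatives. Slc16a9, Gstm2, Mmp8 and Tfrc stayed past their threshold in each of the 19. Counts of higher and lower genes were 85 and 43 with RLE factors, 92 and 50 with upper-quartile factors, 71 and 74 with library totals only, 54 and 22 with no filter, 99 and 60 with the stricter filter, 439 and 323 with DESeq2 (762 genes, among them all 141; 647 adjusted p not given), 84 and 43 with limma-voom, 48 and 47 on log2(FPKM + 1), 47 and 48 on log2(FPKM + 0.1), 11 and 8 on FPKM with no filter, and 18 and 8 at an adjusted p under 0.01. The lower counts with no filter and at the stricter threshold come with their construction, since 26793 genes are then adjusted together or fewer pass. For the other differences the cause was not tested. Leaving out 1 library gave 20 to 94 higher and 10 to 60 lower genes, with fewer samples by construction. In all 6 leave-outs 21 of the 141 genes passed, and in none of them 33. With the replicate block 26 genes were higher and 10 lower, and 15 lists passed. The replicate numbers gave no clear sign of pairing. Correlations of deviations from the group means between libraries of the same number were 0.117, -0.00951 and -0.0607. Of the 6 libraries, 2 correlated best with their own number. With 3 libraries per group these values cannot exclude pairing. Of the 40 lists, 17 passed, against 0 with an estimated correlation, 13 with fry, 16 with library totals only and 7 to 13 with 1 library left out. No list passed in the opposite direction. The adjusted p of the G2 and mitosis list was 0.854 with an estimated correlation, 0.594 with fry, and 1.15e-06 to 0.713 with 1 library left out. That of the G1 to S list was 0.0848 to 0.73 with 1 library left out. Directions that turned belonged to genes and lists that had not passed. With library totals only, log2 fold changes turned to -0.034 for Itgax, -0.014 for Ccr3 and -0.031 for Ddx3y, as did the osteoblast list and the sex-linked check (adjusted p = 0.989 for both). On FPKM with a pseudocount of 1, with or without the filter, Ccr3 was at -0.0079 and Ddx3y at -0.018. With a pseudocount of 0.1 they were at -0.0089 and -0.019. The adipocyte list turned with fry (0.986) and the B cell list with the replicate block (0.965). With 1 library left out, log2 fold changes ranged from -0.38 to 0.13 for Tpm1, -0.14 to 0.22 for Itgax, -0.084 to 0.14 for Ccr3, -0.14 to 0.053 for Pkm, -0.035 to 0.037 for Atp5b and -0.047 to 0.13 for Ddx3y. Adjusted p of lists whose direction turned ranged from 0.0151 to 0.834 for smooth muscle, 0.382 to 0.956 for angiogenic factors, 0.243 to 0.952 for inflammatory activation, 0.238 to 0.911 for dendritic cells, 0.259 to 0.956 for B cells and 0.282 to 0.94 for erythroid cells. They ranged from 0.31 to 0.75 for megakaryocytes, 0.415 to 0.99 for osteoblasts, 0.0984 to 0.952 for osteoclasts, 0.271 to 0.989 for glycolysis, 0.114 to 0.865 for nuclear oxidative phosphorylation and 0.0745 to 0.928 for TGF-beta. The difference in haemoglobin share ranged from -1.92e-05 to 4.79e-05 percentage points. Depth limits genes near 3 fragments per library, among them the cardiomyocyte genes and Vsig4 on PCL.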

Other observations

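The genes in this paragraph were chosen after their values were seen. They were picked one by one and no group of them was tested. Among genes past the threshold, Cd81 was at 168 ± 3.97 CPM on hHVS against 96.9 ± 9.18 on PCL, Clec4n at 53.1 ± 5.14 against 27.4 ± 5.59, Gas6 at 852 ± 63.6 against 603 ± 37.1 and Selenop at 2525 ± 69.1 against 1653 ± 188 (SD, n = 3). Lbp, the gene of lipopolysaccharide-binding protein, was at 3.10 ± 0.803 and 0.266 ± 0.153 CPM, and Tmem119, a microglia marker, at 6.76 ± 1.71 and 1.21 ± 0.344 CPM. Although the fixed matrix list was lower on hHVS with the preset correlation (adjusted p = 0.682 with an estimated correlation), the laminin gene Lama3 rose 2.27-fold, Lamb2 2.33-fold, and the heparanase gene Hpse 2.42-fold. Gsta3, a glutathione transferase gene like Gstm2, rose 2.01-fold. The homeobox gene Dlx3 fell from 2.60 ± 0.61 to 0.112 ± 0.00847 CPM, a level below the floor of a single library. The integrin gene Itgad fell from 3.70 ± 0.379 to 0.907 ± 0.0456 CPM, and the neuropeptide Y gene Npy by a log2 fold change of -0.96. Of the 50-base words of Itgad, 13.5% occur in other genes, first among them Itgax.

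Of the genes past the threshold, 3 had 0 counts in 1 group. Gm20521 (chr 14:54883441-54898137) was at least 120-fold higher on hHVS against the floor over the PCL group, but 96.1% of its 50-base words occur in other genes, first among them Pabpn1 and Bcl2l2. Gm14440 (chr 2:175275125-175286805) was at least 67.0-fold higher, and 100% of its words occur in other genes. Both values are uncertain, since how the counting shared such reads is not given in the sources used here. Hs3st3a1 was at least 9.43-fold lower on hHVS against the floor over that group, and 10.7% of its words occur in Hs3st3b1.

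In the weighing that follows, the tests of the nuclear respiratory chain and of nuclear genes as short as the mitochondrial ones were chosen only after the results were seen. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 141 genes and the highest of the others gave 2, so 1 of the 10, the real split itself, reached 141. The other splits mix both scaffolds within a group, which widens the spread wherever the scaffolds differ. Their low counts therefore do not measure what chance alone would give.

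Mitochondrially encoded genes were higher on hHVS as a list with the preset correlation (adjusted p = 0.279 with an estimated correlation), and 5 of the 13 passed in edgeR. The tables argue against library scaling, since the median log2 fold change of the 13 genes stayed at 0.45 or above under 5 scalings. They also argue against a rise of the whole respiratory chain, since its nuclear subunits had a median of -0.014 (95% interval -0.058 to 0.031). That interval treats genes as replicates and does not cover the spread between libraries. In the list test the nuclear median was -0.069 without PCL replicate 1 and 0.065 without PCL replicate 3, against 0.49 and 0.57 for the mitochondrial genes. The test for RNA breakdown, set beforehand as a trend of log2 fold change with transcript length beyond 0.1 in size in either direction, was met: Spearman's rho across 16282 nuclear genes was 0.135 (95% interval 0.119 to 0.15), though genes are not independent replicates. That bound ignored direction, and the trend ran towards higher values of long transcripts on hHVS. A test was added after this was seen. In it, 4442 nuclear genes within the length range of the 13 genes had a median of -0.069 (-0.081 to -0.060). That is the opposite of the rise. Over the other 9 splits of the libraries, which mix both scaffolds, rho ranged from -0.294 to 0.144. Within the PCL group, rho was -0.345 for replicate 3 minus replicate 1. Meeting the bound thus does not tell a scaffold difference from variation between libraries. A length trend therefore may affect these libraries without explaining the rise, while other differences in RNA handling, RNA brought in with a scaffold and a response of the cells to the scaffold stay open and untested.

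Matrix and stromal genes were lower on hHVS as lists with the preset correlation (adjusted p = 0.682 and 0.279 with an estimated correlation). A candidate explanation is that stromal cells were present in different amounts in single libraries: within groups, 22 matrix genes and 9 smooth muscle genes that share no member deviated together, with a mean correlation of 0.50, against -0.0796 to 0.0743 for random lists. Random lists are a weak baseline, since related genes varied together in other lists too. The estimated correlation between genes was 0.788 in the ribosomal protein list and 0.743 in the G1 to S list. The test therefore cannot tell different amounts of stromal cells from joint regulation of these genes. Of 3 matrix genes chosen after their values were seen, Col1a1 overlapped between the groups, at 65.0, 13.6 and 12.5 CPM in PCL replicates 1, 2 and 3 and at 21.8, 3.55 and 17.0 CPM in hHVS replicates 1, 2 and 3. The other two did not overlap: in the same order Dcn was at 2.35, 2.10 and 1.49 against 0.306, 0.667 and 0.562 CPM, and Col3a1 at 1.91, 1.95 and 9.55 against 0.681, 0.255 and 1.11 CPM. Such variation could give a difference between groups of 3 without the scaffold, and an effect of the scaffold on stromal cells stays open as well.

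Marco and Cd5l were higher on hHVS, and cholesterol synthesis genes lower as a list with the preset correlation (adjusted p = 0.279 with an estimated correlation). Sterol loading of the cells may lower synthesis genes, and then targets of the sterol receptor LXR should be higher: 14 such genes, listed before this test was run but partly members of the lipid list reported above, had a median log2 fold change of 0.12 (camera p = 0.134 with the preset and 0.443 with an estimated correlation), which decides nothing. A larger share of resident-type macrophages may raise Marco, Cd5l and Vsig4 together. To test this, 11 other genes of such cells were taken, some of them in fixed lists reported above. Their median was 0.20 (camera p = 0.00869 with the preset and 0.161 with an estimated correlation). The estimated correlation had been set beforehand as the one to count, so this test was not met. A median below 0, set as the result against it, was not seen either, so it decides nothing. Neither explanation can be told from the other or from a direct response, because members of each list moved both ways in these few libraries. A positive log2 fold change was seen for 10 of 14 LXR targets and 7 of 11 resident macrophage genes.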
